A study of Mus musculus with 23 samples.

How the data were processed

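MicroRNA (miRNA) sequencing was measured in 23 libraries of dissected brain tissue from C57BL/6 mice, 12 from wild type mice and 11 from mice lacking the Cdr1as locus. Cdr1as is a neuronal circular RNA with many binding sites for miR-7 and 1 extensively paired site for miR-671. The 4 regions were cerebellum, cortex, hippocampus and olfactory bulb, with 3 libraries per genotype and region, except that knockout hippocampus had 2 libraries, which carry the replicate numbers 2 and 3. Total RNA was extracted with TRIZOL and libraries were made with the TruSeq Small RNA kit, per the labels' protocols. The labels do not say whether libraries of a group come from separate animals, so the p-values measure the spread between these samples, and libraries of different regions may come from the same mice.

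The authors deposited raw read counts per mature miRNA, 1 table per library, with the same 1915 miRNA names in every table. Reads were mapped to the mouse build mm9, per the submitters' processing notes. The aligner, the counting program, the miRNA annotation version, the adapter trimming and the treatment of reads that match several miRNAs are not given in the sources used here. The counts of miR-486a-5p and miR-486b-5p were equal in 23 of 23 libraries, so the pair shares reads, either counted for both or divided equally. Nearly identical mature sequences, such as miR-7a-5p and miR-7b-5p or the members of the let-7 family, can exchange reads, and their separate values are uncertain to that extent. Coordinates are not printed because the reference at hand was GRCm38 (GENCODE M21), a different build from mm9, and it was used only for the chromosomes and host genes of named miRNAs.

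Total counts per library ran from 2328929 to 13070794, and 741 to 1094 miRNAs had at least 1 count in a library. The lowest total belonged to cortex knockout replicate 3 and the highest to olfactory bulb wild type replicate 1. PCR reads without molecular identifiers are not independent molecules, so counting intervals and floors cover counting error only. No pair of libraries of a group was a duplicate, since their chi-square statistic per degree of freedom ran from 32.5 to 270 over 22 pairs.

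Counts were analysed in R 4.3.3 with edgeR 4.0.16. MiRNAs were kept by filterByExpr with the 8 groups (a minimum count of 10 and a minimum total of 15), which left 669 miRNAs holding at least 99.988% of the reads of any library (669 of the 1459 with a count anywhere). Libraries were scaled with TMM factors, and normalised counts are CPM on those factors. One quasi-likelihood model with a mean for each of the 8 groups was fitted to all 23 libraries. F tests, which are two-sided here, gave knockout against wild type in each region, the mean of the 4 within-region differences, the difference of the genotype effect between regions, and each wild type region against the mean of the other 3. The mean of the other 3 regions is taken on the log2 scale, so a fold against it is over a geometric mean. P-values were adjusted by the Benjamini-Hochberg method over the 669 miRNAs with a threshold of 0.05, and the wild type region comparisons also required a 2-fold difference. Changes are log2 fold changes of knockout over wild type with their standard errors (SE), and group values are mean CPM ± SD.

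The guide arm of a miRNA is the strand loaded into Argonaute and the passenger arm is the other strand of the same precursor. Loading was not measured here. The labels do not follow abundance for miR-671, or for miR-7a in the cerebellum, where the arm called passenger had more counts in wild type. The log2 ratio of guide to passenger counts, with 0.5 added to each, was compared for miR-7a (miR-7a-5p over miR-7a-1-3p plus miR-7a-2-3p), miR-7b and miR-671 by a two-sided exact permutation test that exchanged genotypes within regions, and in each region alone. With 3 libraries against 3 or against 2, the smallest p such a test can give is 0.1. The 3 ratios were adjusted together by the Benjamini-Hochberg method.

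The samples, the tests, the alternatives, 12 miRNA lists and the rule for naming miRNAs were fixed before the data were examined. The lists were Cdr1as-linked miRNAs (both arms of miR-7 and miR-671), the Dlk1-Dio3 imprinted cluster, activity-regulated neuronal miRNAs, neuron-enriched miRNAs, oligodendrocyte miRNAs, microglia and leukocyte miRNAs, red blood cell miRNAs, endothelial and mural miRNAs, choroid plexus and ciliated epithelium miRNAs, the miR-200 family with the miR-183 cluster, the let-7 family, and the chromosome X neighbours of the Cdr1as locus. Each list was tested against the other miRNAs in each of 5 knockout contrasts with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 60 tests, and again with an estimated correlation. Fry was run beside it, which asks whether the members of a list move one way and does not compare them with other miRNAs. Named miRNAs are the Cdr1as-linked list in every comparison, all miRNAs past the threshold in a knockout comparison with at most 30 of them, the 5 with the smallest unadjusted p in a direction with fewer than 5 past the threshold (those at a handful of reads are named without a value), and up to 4 of the most abundant members of a list. In wild type regions they are the 6 largest rises and 3 largest falls with a mean log2 CPM of at least 5 and all 3 libraries of the region on one side of the other 9.

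Alternatives were DESeq2's size factors (RLE), library size only and upper quartile scaling, no filter, a filter of 10 CPM in 3 libraries, the replicate number as a block, limma-voom with and without an animal block, DESeq2 1.42.0, each region fitted alone, pseudocounts of 1 and 5 for the arm ratios, and leaving out each library in turn. A replicate block within each region, one in the cerebellum alone for the arm ratios, a robust fit, a fit without the cortex and a fit without 2 hippocampus libraries were added after seeing the data. In the cerebellum, libraries of the same number in both genotypes deviated from their group means together (r = 0.116, 0.374 and 0.103 across miRNAs, each over 0.1). The numbers were therefore treated as possible pairs there, and the blocked values are given beside the cerebellum result. Pairing is not shown, since libraries of unlike numbers were not compared. Number 2 in cortex (0.140) and number 3 in olfactory bulb (0.139) exceeded numbers 1 and 3 in cerebellum. The correlations are across miRNAs, which are not independent replicates.

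The model was tested on simulated counts for 669 miRNAs drawn from the real means and library sizes, with 100 miRNAs changed by each of 2 sizes. Of the 2-fold changes it recovered 73% in cerebellum, 76% in cortex, 78% in hippocampus, 72% in olfactory bulb and 91% in the average. Of the 1.5-fold changes it recovered 33%, 39%, 35%, 36% and 78% in the same order. False calls made up 2.75%, 4.96%, 3.39%, 2.70% and 6.63% of the calls. The simulation changed far more miRNAs than the 0 to 14 that passed in a real region, which eases the adjustment. It also drew libraries as independent. Recovery in the real comparisons can therefore be lower.

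Targets of miRNAs, other RNA classes and behaviour were not analysed here. Cdr1as itself is too long for small RNA libraries, so these counts cannot check its deletion in any sample.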

Results

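The data are miRNA counts from 4 brain regions of wild type and Cdr1as knockout mice, in 8 groups of 3 libraries each, except 2 for knockout hippocampus. Total counts ran from 2328929 in cortex knockout replicate 3 to 13070794 in olfactory bulb wild type replicate 1. The neuronal miRNA miR-181a-5p was the most abundant in 23 of 23 libraries, with 16.1% to 28.3% of the reads. Brain region set the main differences between libraries, and the first and second principal components held 53.3% and 27.2% of the variance of log2 CPM. The first also parted the cortex libraries by genotype, at 4.52, 2.23 and 3.37 in wild type and -8.62, -5.61 and -7.44 in knockout. On it hippocampus libraries lay between -10.4 and -8.86 and olfactory bulb libraries between 27.7 and 28.6. Cdr1as is a circular RNA and is not counted in miRNA libraries, so its loss cannot be checked in these samples.

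Wild type regions were compared to show where the miRNAs bound by Cdr1as and the region-specific miRNAs are found. The olfactory bulb stood apart by the miR-200 family and the miR-183 cluster, miRNAs of sensory and epithelial cells that also act in olfactory neurogenesis. MiR-141-3p was 709-fold higher there than the geometric mean of the other 3 regions. It was at 9623 CPM there and at 167 CPM in wild type cortex, on average. Its log2 difference was 9.47 (SE 0.35, edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p = 1.49e-15). By the same test miR-200a-3p was higher by 8.85, miR-429-3p by 8.73, miR-200b-3p by 8.63 and miR-183-5p by 8.44 on the log2 scale. For miR-182-5p the level was 210630 ± 12466 CPM (SD, n = 3) against an arithmetic mean of 1582 CPM in the 9 other wild type libraries. The ciliated-cell miRNAs miR-34c-5p (log2 difference -2.62) and miR-34b-5p (-2.56) and the neuronal miR-598-3p (-2.27) were lowest there. In all, 76 miRNAs were higher and 64 lower in the olfactory bulb; with library size only as the scaling the split was 34 higher and 223 lower.

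The cerebellum was marked by miR-10b-5p, a Hox-cluster miRNA of the hindbrain, at 1432 ± 307 CPM (SD, n = 3), a log2 difference of 3.02 (SE 0.26, edgeR and Benjamini-Hochberg adjusted p = 1.85e-09). The growth-restraining pair miR-195a-5p (3.01) and miR-497a-5p (2.73), the p53 target miR-34a-5p (2.84) and the erythroid miR-486a-5p and miR-486b-5p (2.84 each, from shared reads) were also higher there. The largest falls were in miR-429-3p (-6.32), miR-200b-3p (-6.17) and miR-200a-3p (-6.14), against a mean that includes the olfactory bulb. The cerebellum had 110 miRNAs higher and 119 lower; library size only gave 63 and 176, and upper quartile scaling 153 and 92.

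Cortex libraries held more miR-873a-5p (2.11 on the log2 scale, SE 0.16, edgeR and Benjamini-Hochberg adjusted p = 1.11e-09), miR-383-5p (1.98), the imprinted miR-409-5p (1.97), the phosphodiesterase-hosted miR-139-5p (1.81), miR-335-3p (1.70) and miR-31-5p (1.64). They held less of the choroid plexus miRNA miR-204-5p (-2.01), miR-195a-5p (-1.77) and let-7b-5p (-1.22). MiR-204-5p varied within a region, from 2225 to 7391 CPM in wild type hippocampus, against 1240 to 1832 CPM in wild type cortex. The cortex had 67 miRNAs higher and 43 lower; library size only gave 169 and 6, and upper quartile scaling 43 and 87. In the hippocampus miR-344d-3p (2.47, SE 0.14, edgeR and Benjamini-Hochberg adjusted p = 3.53e-11), the synaptic miR-218-5p (1.44), the spine-regulating miR-138-5p (1.21) and miR-376a-5p (1.13) were higher. There miR-183-5p (-5.67), miR-182-5p (-5.64) and miR-129-1-3p (-1.67) were lower. For miR-183-5p and miR-182-5p the mean of the other regions includes the olfactory bulb, and wild type cortex, which may hold olfactory bulb RNA (weighed below). Knockout cortex libraries held 96.3, 302 and 239 CPM of miR-182-5p, against 248, 132 and 152 in wild type hippocampus. The hippocampus had 62 miRNAs higher and 54 lower; library size only gave 155 and 26.

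The level of miR-7, a miRNA of neurons and endocrine cells, differed between wild type regions. The guide arm miR-7a-5p was lower in the cerebellum than in the other regions, with a log2 difference of -1.58 (SE 0.22, edgeR and Benjamini-Hochberg adjusted p = 1.97e-06), and so was its near-identical relative miR-7b-5p (-1.91). In the hippocampus miR-7a-5p (0.92, edgeR adjusted p = 0.000314), miR-7b-5p (0.87) and miR-671-5p (0.93, edgeR adjusted p = 1.40e-06) were higher past the adjusted threshold but by less than 2-fold. The same holds for miR-7b-5p in the olfactory bulb (0.75) and for the lower miR-671-5p in the cerebellum (-0.55) and olfactory bulb (-0.32). None of the 3 passed in the cortex, nor miR-7a-5p in the olfactory bulb. In GRCm38 the miR-7a precursors lie on chromosome 13 in an intron of Hnrnpk and on chromosome 7, that of miR-7b lies on chromosome 17, and that of miR-671 lies on chromosome 5 in an exon of Chpf2. Cdr1 lies on chromosome X, so none of the 4 miRNA genes is near it.

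The knockout was compared with wild type to ask which miRNAs depend on Cdr1as. Averaged over the 4 regions, the guide arms of miR-7 fell and that of miR-671 rose. MiR-7a-5p fell by 1.07 on the log2 scale (SE 0.13, edgeR and Benjamini-Hochberg adjusted p = 1.72e-05), a 2.10-fold lower level. MiR-7b-5p fell by 1.22 (SE 0.14, edgeR and Benjamini-Hochberg adjusted p = 1.56e-05). MiR-671-5p, which can direct slicing of Cdr1as, rose by 0.46 (SE 0.08, edgeR and Benjamini-Hochberg adjusted p = 0.000753). Both miR-7 guide arms were lower in every knockout library than in every wild type library of the same region, in 4 of 4 regions. In a single region, such separation in either direction held for 47 (cerebellum), 51 (cortex), 113 (hippocampus) and 43 (olfactory bulb) of 669 miRNAs.

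The passenger arms of miR-7a and miR-671 did not pass the threshold, nor did that of miR-7b over all miRNAs. The averaged change of miR-7a-1-3p was 0.05 with a 95% interval of -0.10 to 0.21, against -1.33 to -0.80 for miR-7a-5p. MiR-7a-2-3p changed by -0.06 (-0.39 to 0.26) and miR-671-3p by 0.15 (SE 0.09), neither past the threshold. MiR-7b-3p, at low counts, went with its guide arm, lower in 4 of 4 regions at -0.67 (SE 0.21, edgeR and Benjamini-Hochberg adjusted p = 0.258), and 0.00943 when adjusted over the list alone. Of the 7 Cdr1as-linked miRNAs, 3 passed over all 669 and 4 adjusted over the list alone. As a set they were lower by camera in the average (median -0.06, adjusted p = 0.00292 by limma; adjusted p = 0.0467 with an estimated correlation), and did not pass in the cerebellum (camera, adjusted p = 0.524) or cortex (0.562).

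**Figure D1:**
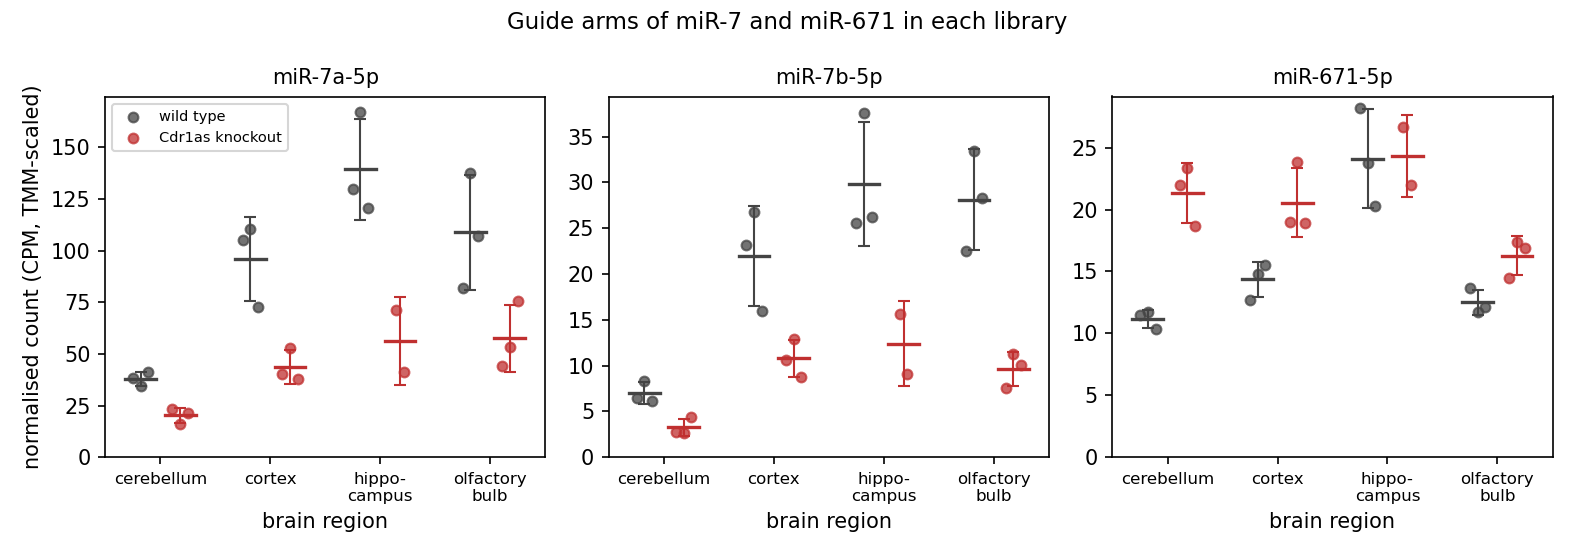
Normalised counts (CPM, vertical axes) of miR-7a-5p, miR-7b-5p and miR-671-5p in each library of the 4 regions, with points for libraries and bars for the mean and SD of wild type (grey) and knockout (red). Knockout points of miR-7a-5p and miR-7b-5p lie below all wild type points in 4 of 4 regions.

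The ratio of guide to passenger arm does not depend on library scaling. For miR-7a it was 2.11-fold lower in knockout (mean log2 difference over 4 regions -1.08; two-sided exact permutation p = 2.5e-05 over 80000 arrangements, adjusted p = 7.5e-05), and lower in 4 of 4 regions. By region the miR-7a difference was -0.86 in cerebellum, -1.21 in cortex, -1.34 in hippocampus and -0.91 in olfactory bulb, and no region alone could give an exact p under 0.1. If the regions of a number come from 1 mouse, the exact permutation of genotype among the numbers gives p = 0.1 for miR-7a, the smallest that design allows, and p = 0.2 for miR-7b and for miR-671. For miR-7b the ratio differed by -0.55 (exact permutation p = 0.0311, adjusted p = 0.0421) and was lower in 3 of 4 regions, with 0.10 in cortex. For miR-671 it differed by 0.32, 1.25-fold (exact permutation p = 0.0421, adjusted p = 0.0421), and was higher in 3 of 4 regions, with -0.22 in hippocampus. The wild type mean log2 ratio of miR-671 was -2.84 in cerebellum, -2.92 in cortex, -2.05 in hippocampus and -3.30 in olfactory bulb. The arm called passenger was therefore the more abundant in each region. For miR-7a the wild type mean log2 ratio was -0.63 in cerebellum and above 0 in the other regions. With exchange within numbered pairs in the cerebellum (chosen after seeing the data) the miR-671 ratio lost its call (exact permutation p = 0.0617), and those of miR-7a (6.25e-05) and miR-7b (0.0313) did not. Leaving out 1 library kept the miR-7a ratio at an exact permutation p of 8.33e-05 or less. The miR-7b ratio lost its call without cortex knockout 2, hippocampus knockout 3, olfactory bulb wild type 2 or 3, or olfactory bulb knockout 2 or 3 (-0.68 to -0.40; exact permutation p up to 0.0842). The miR-671 ratio lost its call without cerebellum wild type 1, 2 or 3, cerebellum knockout 1 or 2, cortex wild type 1 or 2, cortex knockout 2, hippocampus wild type 2 or 3, hippocampus knockout 2, olfactory bulb wild type 3 or olfactory bulb knockout 2 (0.24 to 0.39; exact permutation p up to 0.151).

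**Figure D2:**
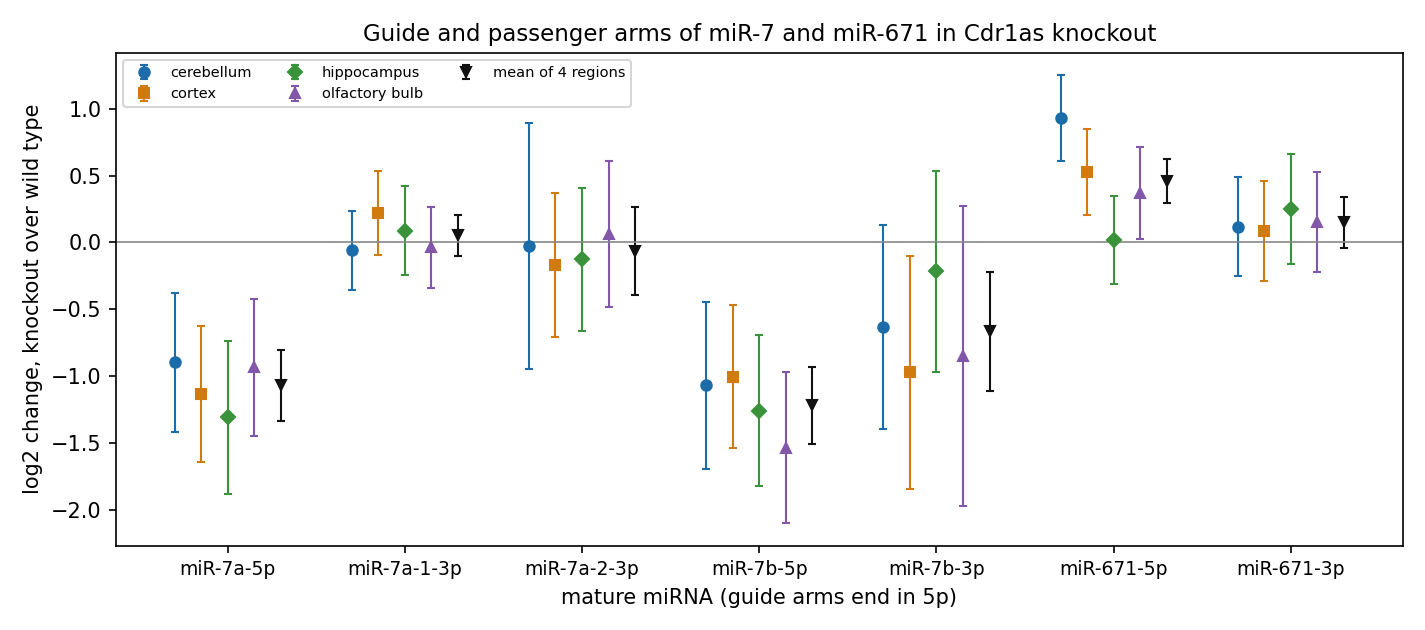
Log2 change of knockout over wild type (vertical axis) for guide arms (5p) and passenger arms (3p) of miR-7 and miR-671 in each region and in the mean of 4 regions, with 95% intervals. The mean change is -1.07 for miR-7a-5p and 0.05 for miR-7a-1-3p.

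In the cerebellum miR-671-5p rose, from 11.2 ± 0.752 to 21.3 ± 2.43 CPM (SD, n = 3 each), a log2 change of 0.93 (SE 0.15, edgeR and Benjamini-Hochberg adjusted p = 0.00435). Its passenger arm miR-671-3p had 0.12. MiR-7a-5p (-0.90, SE 0.25; 38.0 ± 3.38 to 20.3 ± 3.63 CPM) and miR-7b-5p (-1.07, SE 0.30) were lower in 3 of 3 knockout libraries but missed the threshold over all miRNAs (edgeR and Benjamini-Hochberg adjusted p = 0.325 for each), and passed at 0.00459 each when adjusted over the list alone. The list then had 3 members past the threshold against 1. MiR-671-5p was the 1 miRNA of 669 past the threshold, with 13 at an unadjusted p under 0.05. Without wild type replicate 3 its log2 change was 0.88 with an edgeR adjusted p of 0.0623, so that the count was 0. With the replicate number as a block within the region (chosen after seeing the data), 4 miRNAs passed in edgeR with Benjamini-Hochberg adjustment: miR-671-5p (0.93, adjusted p = 0.0134), miR-7a-5p (-0.91, 0.0344), miR-7b-5p (-1.07, 0.0399) and miR-466i-5p (-4.05, 0.0344), a repeat-derived miRNA with 3.26 ± 2.99 CPM in wild type that was named after its values were seen. Among those with the smallest p, miR-344c-3p (0.62), miR-544-5p (0.52), miR-200b-3p (-2.17), miR-429-3p (-2.07) and miR-200a-3p (-1.57) did not pass, the last 3 at -1.19, -0.96 and -0.29 without wild type replicate 2, nor did miR-1927 and miR-1969, at a handful of reads.

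In the cortex both miR-7 guide arms fell, and so did the miR-200 family and the miR-183 cluster. MiR-7a-5p went from 96.2 ± 20.4 to 43.6 ± 8.15 CPM (SD, n = 3 each), a log2 change of -1.13 (SE 0.24, edgeR and Benjamini-Hochberg adjusted p = 0.00801). MiR-7b-5p went from 21.96 ± 5.48 to 10.8 ± 2.04 CPM, a change of -1.004 (SE 0.26, edgeR and Benjamini-Hochberg adjusted p = 0.0418). The edgeR adjusted p of miR-7a-5p rose to between 0.0514 and 0.0714 without wild type replicate 1 or 2 or knockout replicate 1 or 3, and that of miR-7b-5p to between 0.0610 and 0.249 without any of those or knockout replicate 2. Under the other 3 scalings miR-7b-5p did not pass either (edgeR adjusted p between 0.0613 and 0.154). MiR-671-5p was higher by 0.53 (SE 0.15), which did not pass over all miRNAs (edgeR adjusted p = 0.122) and did at 0.00638 when adjusted over the list alone, where 3 members passed against 2. Under upper quartile scaling, which moved the median of all miRNAs to 0.12, miR-671-5p passed (0.66, edgeR adjusted p = 0.0363). MiR-7b-3p (-0.97) and miR-7a-1-3p (0.22) did not pass.

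The larger cortex changes were in miRNAs that mark the olfactory bulb. MiR-182-5p, which lies with miR-183 and miR-96 on chromosome 6 (GRCm38), fell from 3682 ± 1223 to 213 ± 106 CPM, a log2 change of -4.11 (SE 0.40, edgeR and Benjamini-Hochberg adjusted p = 6.94e-07). MiR-183-5p fell from 413 ± 108 to 23.7 ± 13.1 CPM (-4.13, SE 0.37, edgeR and Benjamini-Hochberg adjusted p = 2.68e-07). Of the miR-200 family, whose members lie on chromosomes 4 and 6, miR-200a-3p fell by 3.96, miR-200b-3p by 3.33, miR-141-3p by 4.46, miR-200c-3p by 3.76 and miR-429-3p by 3.45 on the log2 scale, each lower in 3 of 3 knockout libraries. MiR-96-5p (-4.08), miR-200a-5p (-3.54), miR-183-3p (-3.70) and miR-200b-5p (-2.94) fell as well, miR-183-3p and miR-200b-5p with 4 counts each in the knockout libraries. For miR-141-5p, with 57 counts in the wild type libraries and 1 in the knockout, the ratio was 40.02 with a 95% counting interval of 6.90 to 1608. In all, 12 of the 15 tested members fell and 0 rose (12 adjusted over the list alone), while miR-182-3p, miR-200c-5p and miR-96-3p had at most 2 counts in wild type cortex. The list was lower by camera of limma (adjusted p = 1.27e-85; adjusted p = 7.57e-07 with an estimated correlation). The cortex had 14 miRNAs past the threshold, all lower, and 12 to 14 without 1 library; upper quartile scaling gave 1 higher and 13 lower. MiR-6953-3p (1.19), let-7a-2-3p (1.02), miR-15b-5p (0.36) and miR-219a-1-3p (0.77) were higher without passing.

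**Figure D3:**
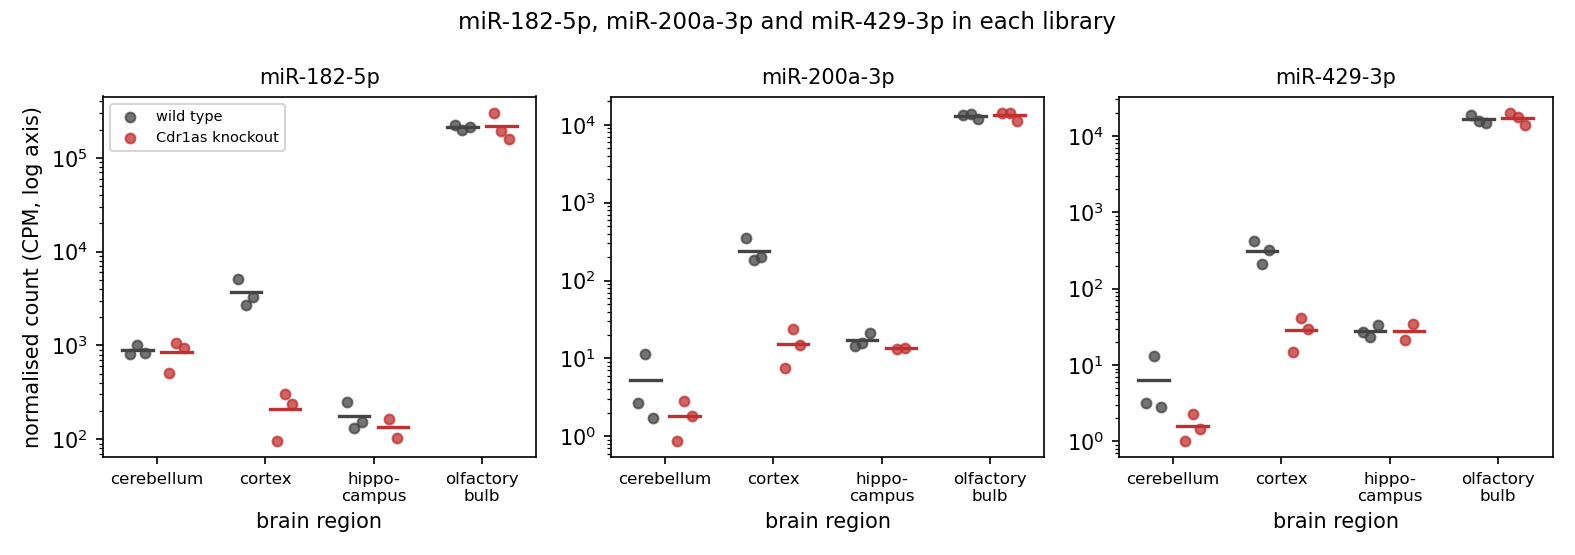
Normalised counts (CPM, log axes) of miR-182-5p, miR-200a-3p and miR-429-3p in each library of the 4 regions, with points for libraries and lines for the means of wild type (grey) and knockout (red). Cortex wild type libraries lie above cortex knockout libraries, at 3682 and 213 CPM on average for miR-182-5p, and the genotypes overlap in the olfactory bulb.

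In the hippocampus, with 3 wild type and 2 knockout libraries, miR-7a-5p went from 139 ± 24.5 to 56.2 ± 21.2 CPM (SD, n = 3 and 2), a log2 difference of -1.31 (SE 0.27), and miR-7b-5p from 29.8 ± 6.76 to 12.4 ± 4.66 CPM (-1.26, SE 0.27). Both were just outside the threshold over all miRNAs (edgeR and Benjamini-Hochberg adjusted p = 0.0509 for each) and passed at 0.000532 each when adjusted over the list alone, where they were the 2 members that passed. MiR-671-5p was at 24.1 ± 3.98 and 24.3 ± 3.32 CPM (0.02). In edgeR 0 of 669 miRNAs passed, with 39 at an unadjusted p under 0.05, while DESeq2 called 3 and limma-voom 2. Without the filter edgeR called more than either (given below). Without wild type replicate 2 the edgeR count was 8 and without knockout replicate 2 it was 3, all lower. As a set the Cdr1as-linked miRNAs were lower by camera of limma, with 4 members lower and 3 higher (adjusted p = 0.0140, and 0.0831 with an estimated correlation). That call was lost without wild type replicate 2 (camera, adjusted p = 0.168) or knockout replicate 3 (0.393).

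The hippocampus also held lower values of choroid plexus and ciliated epithelium miRNAs, markers of ventricular tissue. None of the 9 members passed over all miRNAs and 6 did adjusted over the list alone (median -1.09; camera of limma, adjusted p = 6.34e-05; adjusted p = 0.169 with an estimated correlation; 0.0620 by camera without knockout replicate 2). MiR-204-5p, hosted by Trpm3, went from 5287 ± 2713 to 2491 ± 88.6 CPM (-1.09, edgeR and Benjamini-Hochberg adjusted p = 0.367), and miR-34c-5p differed by -1.37. Wild type replicate 2 had 2225 CPM of miR-204-5p, below the 2429 and 2554 CPM of the knockout libraries, against 6244 and 7391 in the other 2 wild type libraries. MiR-1298-5p (-4.00) and miR-1912-3p (-4.59), which share introns of the choroid plexus gene Htr2c on chromosome X, did not pass. For miR-1298-5p wild type replicate 2 held 112 CPM, against 1816 and 2385 in replicates 1 and 3 and 102 and 76.9 in knockout. The let-7 family of differentiation-linked miRNAs was higher as a set, with 9 of 9 members above wild type and 0 past the threshold, also adjusted over the list alone (median 0.26, and 0.17 to 0.28 under other scalings; camera of limma, adjusted p = 0.000204; adjusted p = 0.675 with an estimated correlation; 0.236 by camera without knockout replicate 3, and 0.214 without wild type replicates 1 and 3, a setting chosen after seeing the data). Its member let-7f-5p had 0.44 (0.12 without knockout replicate 3), and let-7j (0.52, and 0.06 without that library), miR-1843b-3p (0.62) and miR-582-3p (0.31) also did not pass; miR-802-5p was at a handful of reads.

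In the olfactory bulb miR-7b-5p fell from 28.1 ± 5.48 to 9.61 ± 1.88 CPM (SD, n = 3 each), a log2 change of -1.54 (SE 0.27, edgeR and Benjamini-Hochberg adjusted p = 0.00970). MiR-7a-5p went from 109 ± 27.8 to 57.6 ± 16.2 CPM (-0.94, SE 0.25), which missed the threshold over all miRNAs (edgeR adjusted p = 0.365) and passed at 0.00381 when adjusted over the list alone, so that 2 members passed against 1. MiR-671-5p had 0.37 (adjusted over the list alone 0.0844). MiR-7b-5p was the 1 miRNA past the threshold, with 20 at an unadjusted p under 0.05. Without wild type replicate 2 or knockout replicate 1 its edgeR adjusted p was 0.0909 or 0.179, so that the count was 0. The Cdr1as-linked list was lower by camera of limma, with 4 members lower and 3 higher (adjusted p = 0.00359, and 0.0474 with an estimated correlation). That call was lost without knockout replicate 1 (camera, adjusted p = 0.189). MiR-185-3p (-0.77) and, at a handful of reads, miR-466h-3p, miR-802-5p, miR-135a-1-3p, miR-499-5p, miR-194-2-3p and miR-6982-3p had small unadjusted p-values and did not pass.

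The difference between knockout and wild type was then compared between regions. It varied for 11 of 669 miRNAs in edgeR with Benjamini-Hochberg adjustment (26 at an unadjusted p under 0.05), all 11 in the miR-200 family and miR-183 cluster. Those 11 calls rest on the cortex, where wild type libraries may hold olfactory bulb RNA (weighed below). The change of miR-671-5p was smaller in the hippocampus than in the cerebellum by a log2 difference of -0.91 (SE 0.22, edgeR and Benjamini-Hochberg adjusted p = 0.0233 over 42 pairwise tests). Over all regions its difference had an adjusted p of 0.261, and 0.0354 when adjusted over the list alone. For miR-7a-5p and miR-7b-5p no pair of regions differed past the threshold (adjusted p = 0.930 for each pair). In the average over regions 10 miRNAs passed, 1 higher and 9 lower: the 3 guide arms above, and miR-182-5p (-1.13), miR-183-5p (-1.30), miR-200a-3p (-1.47), miR-200b-3p (-1.42), miR-200c-3p (-1.65), miR-141-3p (-1.85) and miR-429-3p (-1.37). Without the cortex (chosen after seeing the data) 3 passed, the guide arms miR-7a-5p, miR-7b-5p and miR-671-5p. MiR-1927, at a handful of reads, miR-1843b-3p (0.33), miR-344c-3p (0.23) and miR-3066-5p (0.51) did not pass.

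The miR-200 family and miR-183 cluster had 7 members lower in the average (11 adjusted over the list alone; camera of limma, adjusted p = 2.75e-30; adjusted p = 0.000835 with an estimated correlation). In the cerebellum, where the miR-200 members are scarce and miR-182-5p was at 888.04 ± 115 CPM (SD, n = 3) in wild type, the list's median was -1.57 with 0 members past the threshold and 2 adjusted over the list alone (camera of limma, adjusted p = 4.28e-07; adjusted p = 0.162 with an estimated correlation). The low values were in miR-200 members, while miR-182-5p had -0.08, miR-183-5p -0.26 and miR-96-5p -0.17. They were smaller without wild type replicate 2, where the median was -0.14 and the list still passed (camera of limma, adjusted p = 0.0146). In the hippocampus the median was -0.35, with 10 members lower, 3 higher and 0 past the threshold (camera of limma, adjusted p = 0.196). In the olfactory bulb, where these miRNAs are abundant, the median was 0.02 with quartiles of -0.03 and 0.05. Its sign there flips with the scaling.

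In the main fit the other lists passed in no knockout contrast. The microglia and leukocyte list in olfactory bulb passed under 1 of 13 alternatives (camera, adjusted p = 0.00204) and reached 0.987 without wild type replicate 2. The Dlk1-Dio3 imprinted cluster of neuronal miRNAs had a median of -0.00 over 90 tested members in the average (camera of limma, adjusted p = 0.948), with miR-434-3p at 0.11 and miR-127-3p at -0.02. The lowest adjusted p of camera over the 5 contrasts was 0.948 for the activity-regulated miRNAs, 0.948 for the neuron-enriched miRNAs, 0.762 for the oligodendrocyte miRNAs, 0.110 for the microglia and leukocyte miRNAs, 0.779 for the red blood cell miRNAs, 0.524 for the endothelial and mural miRNAs, 0.341 for the chromosome X neighbours of the locus and 0.780 for the Dlk1-Dio3 cluster. Averaged changes were 0.09 for miR-132-3p, 0.05 for miR-138-5p, -0.11 for miR-124-3p, 0.07 for miR-128-3p, -0.10 for miR-338-3p, -0.08 for miR-21a-5p, -0.01 for miR-451a, 0.03 for miR-143-3p, -0.32 for miR-504-5p and -0.12 for miR-505-3p, with 0 past the threshold. Of the 60 combinations of list and contrast, 8 passed with camera, 4 of these with an estimated correlation. Fry, which tests a list against no change and not against other miRNAs, passed in 3: the Cdr1as-linked list in the average (adjusted p = 0.00495), and the miR-200 family with the miR-183 cluster in cortex (1.20e-06) and in the average (0.00111). In 14 combinations the list's median, mean and test differed in sign, none of them past the threshold.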

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

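The tests of scaling, of the list in the olfactory bulb, of the arm ratio and the summed miR-7 as explanations, and the fit without the cortex were chosen only after the result was seen.

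The difference between knockout and wild type varied between regions for 11 of 669 miRNAs, all in the miR-200 family and miR-183 cluster, and for miR-671-5p when adjusted over the list alone. For the 11, a genotype effect cannot be told apart from olfactory bulb RNA in the wild type cortex libraries (weighed below). The gap between the regions with the largest and the smallest log2 change was 4.10 for miR-183-5p (edgeR with Benjamini-Hochberg adjustment, adjusted p = 6.76e-05), 4.17 for miR-182-5p (8.02e-05) and 3.35 for miR-200b-3p (0.000408). It was 3.69 for miR-200c-3p, 5.97 for miR-141-5p (which rests on 1 count in knockout cortex), 4.48 for miR-141-3p and 3.98 for miR-200a-3p (0.000705 each), 3.50 for miR-429-3p (0.000793), 4.38 for miR-96-5p and 3.83 for miR-200a-5p (0.00105 each), and 3.67 for miR-183-3p (0.0419, a call lost under 25 of 35 alternatives). Without the cortex, an alternative chosen after seeing the data, 0 miRNAs differed between regions in edgeR. For miR-671-5p the gap was 0.91, with an adjusted p of 0.261 over all miRNAs and 0.0354 when adjusted over the list alone, and it lay between cerebellum and hippocampus.

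In cortex 14 miRNAs passed against 0 in the highest of the other 9 splits of the 6 libraries, and these splits are too few for a share under 0.05 (1 of 10). The same limit holds in the cerebellum, with 1 against a highest other of 1 (2 of 10 splits as large). It holds in the olfactory bulb too, with 1 against 6 (2 of 10). There the split that joined wild type replicate 1 with knockout replicates 2 and 3 gave the 6, and the cause was not tested. In the cerebellum the 4 splits that part all 3 numbered pairs gave 1 for the real one and 0 for the others. For the averaged count, 10 stood against a highest other of 11 (3 of 100 drawn splits as large, the real one included). That share is under 0.05 if the libraries are independent, but a drawn split reached 11, so chance is not excluded. The draws exchanged the cerebellum libraries without regard to their numbers. Of the 10, 7 were in the miR-200 family and miR-183 cluster. If the regions of a number come from 1 mouse, exchanging whole mice allows no share under 0.1. For the difference between regions the splits cannot decide, with 11 against 21 (10 of 100): of the 9 other splits as large, 7 part the cortex libraries by genotype, as do 7 of the 99 drawn, and so hold the same cortex difference. The highest count among splits that do not was 15. Between wild type regions the splits cannot decide, though each share was under 0.05. They mix regions within a group, which can raise the spread in the model, and the median count of the draws was 0. Cerebellum had 229 against a highest other of 92 (1 of 100) and hippocampus 116 against 81 (1). Olfactory bulb had 140 against 111 (1), and cortex 110 against a larger 215 (3).

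The lower miR-200 family and miR-183 cluster in knockout cortex was weighed first. Library scaling is argued against, since the list's median change stayed at or below -3.57 under 4 scalings, and so is a loss in every knockout region, since its median in the olfactory bulb was 0.0179. The miR-200 sum was 2.54%, 1.37% and 1.76% of the wild type olfactory bulb level in the wild type cortex libraries, and 0.0754%, 0.218% and 0.137% in the knockout ones. A candidate source is a small share of olfactory bulb RNA in wild type cortex, about 1.65% by miR-182-5p and 1.49% to 2.20% by the 12 members that fell, either from dissection or from reads passed between libraries. It cannot be told apart from a genotype effect in cortex: outside the list the slope of observed on predicted change was 2.40 over 3 miRNAs (miR-375-3p, miR-455-5p and miR-490-3p), whose predicted changes (median -0.09) are smaller than their errors (median SE 0.19).

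The lower miR-7 guide arms were weighed next. For miR-7a, lower transcription or processing of the precursor is argued against by the guide to passenger ratio, lower by a log2 difference of -1.08 while miR-7a-1-3p changed by 0.05. For miR-7b it stays open: the ratio differed by -0.55, but the 95% interval of the passenger arm (-1.11 to -0.22) overlaps that of the guide (-1.50 to -0.93), and the cortex ratio was 0.10. Reads moved between miR-7a-5p and miR-7b-5p are argued against by their sum, whose log2 change was -0.95 or lower in each of the 4 regions, and library scaling by an averaged miR-7a-5p change of -1.03 or lower under 4 scalings. What lowers the miR-7a guide arm without Cdr1as stays open, since guide stability was not measured.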

How the results depend on the processing

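The replicate block within each region and that in the cerebellum alone, the robust fit, the fit without the cortex and that without 2 hippocampus libraries were chosen after the data were seen. Counts are miRNAs past the threshold in edgeR unless another tool is named, and where no reason is given the cause was not tested.

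Of the values of single knockout changes under the alternatives, 2921 kept their direction and side of the threshold, 31 were weaker, 39 stronger, and 112 changes that had not passed changed sign. The averaged changes of miR-7a-5p, miR-7b-5p and miR-671-5p held under 36 of 36 alternatives. Adjusted p reached 0.0013 for miR-7a-5p in edgeR without the cortex. By limma-trend on means per genotype and number it reached 0.00217 for miR-7b-5p and 0.0338 for miR-671-5p. Those means leave out the hippocampus, and the miR-671-5p change was then 0.57. In the cerebellum miR-671-5p held under 15 of 17 (adjusted p up to 0.174, in the region alone). In cortex miR-7a-5p held under 13 of 17 and miR-7b-5p under 7 of 17, and in the olfactory bulb miR-7b-5p under 14 of 17. In the hippocampus both miR-7 guide arms passed under 7 of 17. Of the region differences of single miRNAs 374 held and 46 were weaker, 25 of them for miR-183-3p.

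Library size only gave 175 for wild type cortex, 181 for hippocampus and 257 for olfactory bulb, by shifting the median of all miRNAs (0.52, 0.55 and -0.71). The 10 CPM filter, which tests fewer miRNAs, gave 75 for wild type hippocampus. No filter gave 12 in cerebellum, 20 in hippocampus, 4 in olfactory bulb, 21 in the average and 31 for the region difference. DESeq2 gave 3 in cerebellum and 3 in hippocampus, limma-voom 2 in hippocampus and 4 for the region difference, and the robust fit 2 in hippocampus. Each region alone, with fewer samples, gave 0 in cerebellum and 0 in olfactory bulb. Without the cortex the average had 3 and the region difference 0, and the miR-671 ratio was 0.28 (exact permutation p = 0.136). Upper quartile scaling moved the median of all miRNAs in the cortex knockout comparison to 0.12.

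With the replicate number as a block, hippocampus had 2, and limma-voom with an animal replicate block gave 5 for the region difference. The within-region replicate block gave 4 in cerebellum, 2 in hippocampus and 2 in olfactory bulb, and changed no other count of calls by over 1.5 times. With blocked pairs the miR-7b ratio was -0.53 (exact permutation p = 0.0967) and the miR-671 ratio 0.34 (0.0527). With the block in the cerebellum alone the miR-671 ratio stayed 0.32 (0.0617). Outside the cerebellum 2 of 8 pairs had r over 0.1, with a range of -0.216 to 0.140, and in no region were the numbers shown to pair samples.

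Leaving out 1 library gave 0 to 1 in cerebellum, 12 to 14 in cortex, 0 to 8 in hippocampus, 0 to 1 in olfactory bulb, 9 to 12 in the average and 10 to 13 for the region difference. Where 1 library was left in a group, it was assumed to vary like the other groups. The wild type counts were 214 to 236, 95 to 121, 111 to 119 and 136 to 153 for cerebellum, cortex, hippocampus and olfactory bulb. The arm ratios were -1.16 to -1.01 for miR-7a, -0.68 to -0.40 for miR-7b and 0.24 to 0.39 for miR-671.

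Of the list results 856 held, 15 were weaker, 20 stronger and 92 not past the threshold changed sign. One reversed: the choroid plexus list in hippocampus without wild type replicates 1 and 3 (camera's adjusted p = 0.698), with 1 wild type library left. The averaged let-7 result (camera's adjusted p = 0.0599) passed under 12 of 30 alternatives (down to 0.00645), among them library size only and leaving out any of several single libraries, and reached 0.988 with an estimated correlation. Depth limits miR-141-5p, miR-183-3p and miR-200b-5p in knockout cortex, at 1, 4 and 4 counts.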

Other observations

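The tests on choroid plexus miRNAs were chosen after the result was seen.

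In the hippocampus the choroid plexus list was lower in knockout by camera of limma (adjusted p = 6.34e-05; adjusted p = 0.169 with an estimated correlation), and the miRNAs of the Htr2c introns, which are outside the list, varied with it. Wild type replicates 1, 2 and 3 held 1816, 112 and 2385 CPM of miR-1298-5p, and knockout replicates 2 and 3 held 102 and 76.9. For miR-34c-5p the values were 2185, 671.5 and 3175 CPM in wild type and 686 and 870 in knockout, and for miR-448-3p 240, 17.8 and 254 against 18.3 and 14.7. Cerebellum wild type replicate 3 had 27.7 CPM of miR-1298-5p against 1310 and 1706 in the other wild type cerebellum libraries.

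Over the 23 libraries, deviations from the group means of the list and of the Htr2c miRNAs went together (Pearson's r = 0.833, permutation p = 0.00037; Spearman's rho = 0.839, permutation p = 0.00144; 100000 resamples, 1 relation tested). Without the 2 farthest libraries, cerebellum wild type replicate 3 and hippocampus wild type replicate 2, r was 0.788. Choroid plexus tissue that differs between dissected samples is a candidate source. Members of the list were also correlated singly with the Htr2c miRNAs, without a test. The arms of miR-34b and miR-34c had r of 0.77 to 0.87, miR-204-5p 0.68, miR-211-5p 0.53 and miR-204-3p 0.46. The members miR-449a-5p and miR-449c-5p did not move with the Htr2c miRNAs (r = -0.20 and -0.47). A genotype effect stays open, since without wild type replicates 1 and 3 the list's median difference was 0.17 (limma's camera with an estimated correlation, adjusted p = 0.990), with 1 wild type library left.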
